A study of Macaca mulatta with 6 samples.

How the data were processed

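Polyadenylated RNA from neurons purified from the cortex of rhesus monkeys was sequenced in 6 libraries, 3 from animals given morphine and 3 from animals given saline, per the labels. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name Bowtie2 2.1.0, StringTie, DESeq2 1.18.1 and the human build hg19, with no role for each. The gene identifiers in the deposited tables are those of rhesus genes, so the build and annotation used for counting are not settled by the sources used here, and no gene coordinates are given. Whether counting used strand is not given in the sources used here.

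The authors deposited a table of 23191 genes with normalized counts per library, a signal in which reads were divided by a size factor per library, per the file headers and the values. The same table holds the authors' log2 fold changes and their standard errors, their test statistic (a score) and their p-values, raw and adjusted. A second table deposited by the authors holds a subset of 2332 genes with the same columns. All columns of library values were mapped to a sample. Dividing each library's values by the worth of 1 read gave whole numbers within 0.001 for 100% of values in each library, so reads per library could be recovered. Recovered depth was 31238653, 36345095 and 34350049 reads in morphine libraries 1, 2 and 3 and 34495925, 33969814 and 32188657 in saline libraries 1, 2 and 3. Floors for counts of 0 cover counting error only. Symbols were taken from a table of gene names, which matched 15436 of 23191 identifiers (66.6%), and 771 of the changed genes had no symbol.

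Because the deposited values are normalized, the test was limma 3.58.1 in R 4.3.3 on log2(value + 1), without an intensity trend and without robust estimation, with group as the only term. Genes with a mean normalized count of at least 10 were tested, 16595 in all. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was said to rise or fall at an adjusted p under 0.05. For each gene list the p-values were also adjusted over the list alone. The limma estimate of prior degrees of freedom was 1.27, so that genes borrowed little from each other. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation.

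The 31 lists and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among changed genes with an official symbol, a mean above the median of tested genes and groups that do not overlap. It also took up to 4 members of each list with the smallest adjusted p, and OPRM1, OPRD1, OPRK1, PENK, PDYN, FOS, BDNF, FKBP5 and CTCF. GFAP, ITGAM, P2RY12, PTPRC, MBP, KIF5A and CAMK2A were named after their values had been seen. The list of opioid peptides and receptors, for which 4 members were measured, the clustered protocadherins and the blood cell markers were too short for camera. Identifiers without a symbol belong to no list. Some genes that the rule takes are not reported here.

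Libraries of a group were compared before they were averaged. Over genes with at least 50 summed reads, the mean chi-square of pairs within a group lay between 17.5 and 23.8 (medians 2.6 to 3.19), where sampling noise alone gives a mean of 1 and a median of 0.455. Libraries within a group thus differed by more than sampling noise, which does not show whether they came from the same RNA or animal. The edgeR 4.0.16 estimate of the biological coefficient of variation was 0.16. On simulated data with the means and library sizes of these samples and 200 changed genes of 16595, the limma test recovered 2% of genes changed by 1.5 fold and 26% of those changed by 2 fold, with 1 false call. The edgeR test recovered 32% and 63%, with 11 false calls. Most true changes of these sizes were thus missed by limma when few genes were changed. The camera test called the 1 shifted list and 0 of the other simulated lists, among 21 lists of 30 genes. All genes of the shifted list moved by 0.5 on the log2 scale, and genes were drawn independently. The check thus does not show how camera does on lists with correlated or unevenly changed members.

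Alternatives were other scalings (TMM from edgeR, upper quartile), no filter and a minimum of 50, pseudocounts of 0.5 and 5, the replicate number as a block, each library left out, an adjusted p under 0.01, DESeq2 1.42.0 on the recovered reads and the authors' deposited comparison. The edgeR quasi-likelihood test on the recovered reads and limma with an intensity trend were added after the data had been seen. In all libraries 100% of values came out whole, and DESeq2 called 5781 genes and edgeR 5636 genes on these reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Effects of GC content and gene length were not tested, because no annotation of the build was used here.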

Results

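Gene expression was measured by sequencing of polyadenylated RNA in 6 libraries of neurons purified from the cortex of male rhesus monkeys (Macaca mulatta). There were 3 libraries from animals given morphine, an opioid that acts mainly through the mu opioid receptor, and 3 from animals given saline. Morphine was injected under the skin 3 times a day for 90 days, at 3 mg/kg at first and at 15 mg/kg from day 29. The study set out to follow changes in the folding of chromatin after long exposure to morphine, and these libraries are its expression measurements. The protocol names 4 monkeys, 2 in each group, while the description labels carry 1 code for all libraries of a group. With 3 libraries from at most 2 animals, at least 2 libraries of each group share an animal, and all 3 may come from 1. The p-values over libraries are therefore too small as tests over animals and measure only the spread between these samples, and treatment cannot be separated from differences between animals. Recovered reads per library lay between 31238653 and 36345095, and the 10 most abundant genes took between 3.76% and 4.06% of them. Log2 values correlated across genes at 0.972 to 0.978 within groups and at 0.950 to 0.957 between groups, where genes are not independent replicates. The first principal component held 45.7% of the variance and separated the groups.

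The largest rises with morphine were in NAV1, SYNDIG1L, BAIAP3, TMC6 and CCN3, and the largest falls were in SLC6A15, SLC13A3, COL20A1, TM4SF18 and SLC19A3, among abundant genes with a symbol. SYNDIG1L (ENSMMUG00000038996), a relative of a protein that promotes synapse formation, went from 498.7 ± 6.94 to 3256 ± 185 normalized counts (mean ± SD, n = 3 libraries per group). That is a log2 fold change of 2.70 ± 0.0603 (SE), with an adjusted p of 0.000432 in limma. SLC6A15 (ENSMMUG00000013650), a carrier of neutral amino acids, fell by 1.77 ± 0.0743 on the log2 scale, from 1031 ± 70.6 to 302.0 ± 14.6 normalized counts. SLC13A3, a carrier of dicarboxylates, fell by 1.55 and SLC19A3, a carrier of thiamine, fell by 1.48.

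Across all 16595 genes tested, 2143 rose and 2488 fell at a limma adjusted p under 0.05, which is 27.9% of the genes. Rises made up 46.3% of the changed genes, and 50.7% of them when the libraries were scaled by the upper quartile. Most changes were small: the median absolute log2 fold change of changed genes was 0.487. There were 798 genes that rose and 928 that fell by over 1.5 fold, and 370 and 248 by over 2 fold. The 3 values of a group all lay above the 3 of the other for 8076 genes (48.7%), where chance gives 10% for independent libraries. Libraries that share an animal are not independent, so differences between animals alone could raise that share. BAIAP3, which takes part in dense-core vesicle release, rose by 1.86 on the log2 scale, and the matricellular protein gene CCN3 rose by 1.74. TMC6 rose by 1.75, ENDOU by 1.58, ZNF337 by 1.55, IGFBP3, a binding protein of insulin-like growth factors, 2.82 fold, PTPRU by 1.46 on the log2 scale and the cilium gene NPHP4 by 1.42. TRIM17 rose by 1.62 with a wide spread in the morphine libraries (1070 ± 345, n = 3 libraries). NAV1 rose by 4.14 ± 0.831 (SE), from 88.99 ± 85.2 to 1086 ± 135 normalized counts, and its saline libraries differed widely. NAV1 did not pass in limma without morphine replicate 1, 2 or 3 (adjusted p = 0.0681, 0.0659 and 0.0638) or without saline replicate 3 (adjusted p = 0.0598). Further falls were by 1.52 in the collagen gene COL20A1, 2.83 fold in TM4SF18, by 1.43 in CEP95 and by 1.39 in KCTD16, an auxiliary subunit of GABA-B receptors. LAD1 fell by 1.37, TMEM196 by 1.29, GALNT1 by 1.26 and ANGPT1, a ligand of the TEK receptor of vessels, by 1.24. The globin gene HBE1 fell by 1.32, a value that is uncertain because near-identical globin copies can share reads. Leaving out 1 library lowered the count of changed genes from 4631 to 2686, 2536 or 2760 (without morphine replicate 1, 2 or 3), to 3073 or 2894 (without saline replicate 1 or 2) and to 3181 (without saline replicate 3).

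**Figure D1:**
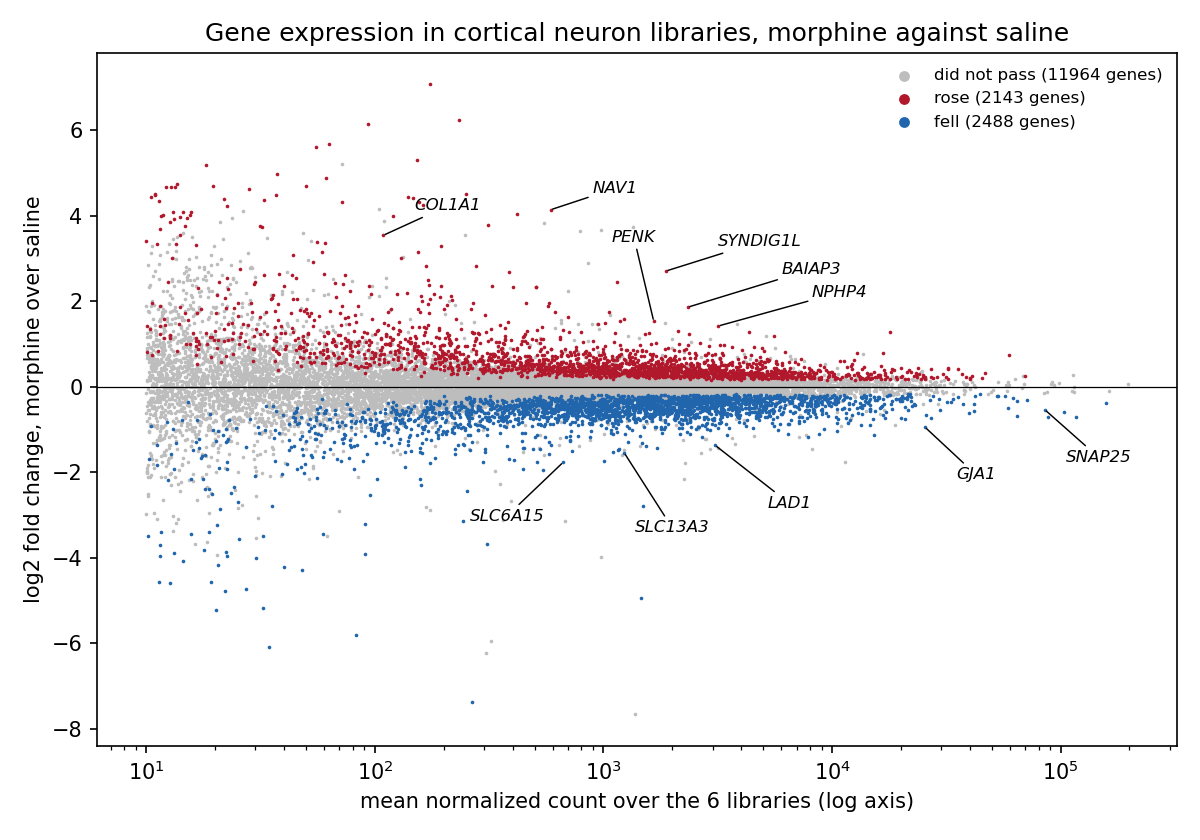
Log2 fold change of each of the 16595 tested genes, morphine over saline (vertical axis), against its mean normalized count over the 6 libraries (horizontal log axis), with 2143 genes that rose in red, 2488 that fell in blue and the others in grey. NAV1 lies highest of the labelled genes at 4.14, and SLC6A15 lowest at -1.77.

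The opioid peptide genes PENK and PDYN rose with morphine, in libraries where 8 of 13 astrocyte markers fell, 6 of 12 microglia markers rose and 6 of 14 pan-neuronal markers fell. PENK (ENSMMUG00000006775), the precursor of the enkephalins, went from 853.1 ± 52 to 2464 ± 89.6 normalized counts (n = 3 libraries per group), a log2 fold change of 1.53 ± 0.068 (SE) with a limma adjusted p of 0.00114. PDYN, the precursor of the dynorphins, rose by 0.60 ± 0.0915, and OPRL1, the nociceptin receptor, rose by 0.39 ± 0.0667. OPRL1 did not pass in limma without morphine replicate 1 or 2 (adjusted p = 0.0509 and 0.0525). Of the 4 list members measured, 3 rose, and 3 rose when adjusted over the list alone. PNOC, the nociceptin precursor, did not pass the test (log2 fold change -0.04 ± 0.0818). The mu receptor gene OPRM1 was below the level for testing: it had 0 reads in each morphine library and in saline library 1, and 4 and 5 reads in saline libraries 2 and 3. A count of 0 allows up to 3 reads in a library. OPRD1 and OPRK1 were not analysed here.

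Markers of several cell types moved with the group. Over all tested genes 27.9% were called, and the counts in this and the following lists are to be read against that share. With a minimum mean of 50 normalized counts, 5026 of 14024 genes were called, which is a higher share. For lists of abundant genes 27.9% is therefore too low a reference. Of 13 astrocyte markers measured, 8 fell and 2 rose. GJA1, the main gap junction protein of astrocytes, went from 33500 ± 1310 to 17418 ± 339 normalized counts (n = 3 libraries per group) and the glutamate carriers SLC1A3 and SLC1A2 fell by 0.58 and 0.68, while AGT rose by 0.80 and GFAP by 0.41. Of 12 microglia markers, 6 rose and 2 fell: TREM2 rose by 1.69, ITGAM by 1.16, C1QC by 1.01 and CSF1R, the receptor that sustains microglia, by 0.87, while P2RY12 fell by 0.47 and PTPRC by 0.51. PTPRC did not pass in DESeq2 (adjusted p = 0.0741) or in limma without morphine replicate 2 (adjusted p = 0.058) or saline replicate 1, 2 or 3 (adjusted p = 0.0658, 0.0707 and 0.0522). Adjusted over the list alone, 8 astrocyte markers fell and 2 rose, and 7 microglia markers rose and 3 fell. Among 17 endothelial and mural cell markers 5 rose and 3 fell, with the same counts adjusted over the list alone. The collagen genes COL1A1 and COL1A2 rose by 3.54 and 2.34 and the smooth muscle actin ACTA2 by 0.78, while the pericyte gene RGS5 fell by 0.68. Of 8 oligodendrocyte precursor markers 4 rose and 0 fell (7 and 1 adjusted over the list alone), with OLIG2 up by 0.52 and BCAN by 0.28. In the 6 fits without 1 library 2 or 3 of them rose, and the rises of CSPG4 and TNR did not pass in any of these fits (adjusted p from 0.0634 to 0.127). Of 13 oligodendrocyte markers 5 rose and 3 fell, also when adjusted over the list alone: MAL rose by 0.61 and CNDP1 by 0.56, and UGT8, an enzyme of myelin lipid synthesis, fell by 0.50. Without 1 library 2 to 4 oligodendrocyte markers rose and 0 to 2 fell, and UGT8 did not pass without morphine replicate 1 or 2 or saline replicate 1 (adjusted p = 0.054, 0.0548 and 0.0501). Of 5 choroid plexus and ependymal markers 2 rose and 2 fell, also when adjusted over the list alone, among them FOXJ1 (rose by 1.40) and CLIC6 (fell by 1.40), but 1 rose in DESeq2, in edgeR and in limma without morphine replicate 1 or 2 or saline replicate 1 or 2. Of 4 blood cell markers the B cell gene MS4A1 rose by 1.81 and the T cell gene CD3E fell by 0.72, also when adjusted over the list alone. Both were low: MS4A1 went from 7.41 ± 3.15 to 27.3 ± 2.65 normalized counts and CD3E from 54.7 ± 6.53 to 33.0 ± 5.54 (n = 3 libraries per group). CD3E did not pass in DESeq2, in edgeR or in limma without morphine replicate 2 or 3 or saline replicate 1 or 3 (adjusted p = 0.056, 0.0703, 0.0706 and 0.0718).

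Transcripts of glia and of neurons were both among the most abundant in these libraries labelled as neurons. MBP, a protein of myelin, had the highest mean of all genes, with 202716 ± 883 normalized counts in morphine and 192902 ± 3180 in saline libraries (n = 3 libraries per group). The neuronal genes KIF5A and CAMK2A ranked 2 and 5, with means of 163203 and 114830 normalized counts over the 6 libraries, the astrocyte gene SLC1A3 ranked 9 and the neuronal SNAP25, with 69525 ± 943 in morphine and 101045 ± 4230 in saline libraries, ranked 16. Of 14 pan-neuronal markers 6 fell and 3 rose, also when adjusted over the list alone. The neurofilament genes NEFL and NEFM fell by 0.73 and 0.57, SNAP25 by 0.54 and MAP2 by 0.37. Without 1 library 5 or 6 of them fell and 0 rose, while 5 rose and 6 fell in DESeq2 and in edgeR. Of 15 excitatory neuron markers 5 fell and 0 rose (5 and 1 adjusted over the list alone), among them NEFH (fell by 0.45) and NRGN (fell by 0.22). Without 1 library 2 or 3 of them fell, and NRGN did not pass in any of the 6 fits (adjusted p from 0.0539 to 0.0826). Of 14 inhibitory neuron markers 3 rose and 1 fell (4 and 2 adjusted over the list alone): NPY rose by 0.77, SST by 0.53 and LAMP5 by 0.42, and VIP fell by 0.57. LAMP5 did not pass without morphine replicate 1 or 3 or saline replicate 2 or 3 (adjusted p = 0.0705, 0.0711, 0.0697 and 0.065), and 5 of the 14 rose and 2 fell in DESeq2.

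Synaptic gene groups moved in both directions, in libraries where astrocyte markers fell and microglia markers rose as given above. Neuronal markers moved too: 6 of 14 pan-neuronal markers fell and 3 rose, and 5 of 15 excitatory neuron markers fell and 0 rose. Among 21 genes of GABA receptors, synthesis and transport, 7 fell and 1 rose (8 and 2 adjusted over the list alone). The receptor subunit GABRG1 fell 2.27 fold and GABRB1 fell by 0.43 on the log2 scale, whereas GABRD, a subunit of extrasynaptic receptors, rose by 0.40. There were 2 rises with upper-quartile scaling and 3 in DESeq2 and in edgeR. Of 42 genes of glutamate receptors and the postsynaptic density, 6 rose and 8 fell (8 and 11 adjusted over the list alone), but 8 rose and 7 fell with upper-quartile scaling, 8 rose and 13 fell in DESeq2 and in edgeR, and 3 to 5 rose and 2 to 5 fell without 1 library. GRIN1, the obligatory NMDA receptor subunit, rose by 0.43, GRIK4 by 0.82 and GRM4 by 0.74, and GRM3 fell by 0.46. Of 33 genes of presynaptic vesicle release 4 rose and 6 fell (5 and 6 adjusted over the list alone), but 9 rose and 8 fell in DESeq2, 8 rose and 8 fell in edgeR, and 0 to 2 rose and 4 to 6 fell without 1 library, with SYT4 down by a log2 fold change of -0.63 and SYT1, a calcium sensor of vesicle release, by -0.29. Among 39 voltage-gated ion channel genes 6 rose and 3 fell (5 and 3 adjusted over the list alone), but 5 rose and 5 fell with TMM scaling, 10 rose and 7 fell in DESeq2, and 3 or 4 rose and 2 to 4 fell without 1 library. The calcium channel genes CACNA1H, CACNA1B and CACNA1C rose by 0.78, 0.59 and 0.49, and the potassium channel gene KCNQ5 fell by 0.82. Of 23 monoamine and acetylcholine receptors 1 rose and 3 fell, also when adjusted over the list alone: the dopamine receptor DRD2 rose by 1.06 (adjusted p = 0.0519 in limma without morphine replicate 2), and the serotonin receptor HTR2A fell by 1.01, CHRNA4 by 0.84 and CHRM3 by 0.56. Of 20 neuropeptide genes 7 rose and 5 fell (8 and 6 adjusted over the list alone), led by CARTPT, which rose by 1.97, and SCG3, a granin of secretory granules, which fell by 1.03. Without 1 library 4 or 5 of them rose and 4 or 5 fell.

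In the same libraries, where astrocyte and microglia markers moved as given above, of 40 G protein and cAMP signalling genes 5 rose and 13 fell (7 and 14 adjusted over the list alone), with a camera p of 0.321, and 3 or 4 rose and 6 to 10 fell without 1 library. RGS4 and RGS7, which speed the shutting off of G proteins, fell by 0.77 and 0.55, while RGS14 rose by 0.86 and PPP1R1B, a phosphatase inhibitor regulated by dopamine, rose by 0.50. Of 20 immediate early genes, which neuronal activity induces, 0 rose and 4 fell, also when adjusted over the list alone, while 7 fell in edgeR and 1 or 2 fell in the 6 fits without 1 library. EGR2 fell by 0.70, KLF10 by 0.41, ARC by 0.23 and FOSL2 by 0.24, although FOSL2 did not pass with upper-quartile scaling or in DESeq2. ARC and FOSL2 did not pass in any of the 6 fits without 1 library (adjusted p from 0.0537 to 0.0766 and from 0.0709 to 0.105), and KLF10 did not without morphine replicate 1 or saline replicate 1, 2 or 3 (adjusted p = 0.0534, 0.0642, 0.0673 and 0.0578). FOS did not pass (log2 fold change -0.05 ± 0.0623). BDNF fell by 0.63 and the adaptor gene FRS2 by 0.56, the only changes among 14 neurotrophin signalling genes in limma, with 0 rises and 2 falls adjusted over the list alone, and 2 rises and 3 falls in DESeq2. Of 11 glucocorticoid-responsive genes NFKBIA rose by 0.56 and PER1 by 0.35, with 2 rises and 0 falls adjusted over the list alone and 5 rises in DESeq2 and in edgeR, while FKBP5 did not pass (log2 fold change 0.12 ± 0.115).

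Of 41 genes of chromatin architecture, the topic of the study, 13 fell and 4 rose (15 and 4 adjusted over the list alone), and 10 or 11 fell and 1 to 3 rose without 1 library. The list did not pass as a whole (camera adjusted p = 0.149, and adjusted p = 0.479 with an estimated correlation), and astrocyte markers fell and microglia markers rose in these libraries as given above. STAG2, a subunit of cohesin, the ring complex that holds chromatin loops, went from 1770 ± 85.2 to 1065 ± 27.5 normalized counts (n = 3 libraries per group). PDS5B, a regulator of cohesin, fell by 0.56, TOP2B by 0.59 and HMGB1 by 0.44, where processed copies of HMGB1 could share reads. CTCF, the DNA-binding protein at loop anchors, did not pass the test (log2 fold change -0.01 ± 0.0762). Of 51 histone and DNA modifying enzymes 14 rose and 5 fell (15 and 5 adjusted over the list alone; camera adjusted p = 0.0681, and adjusted p = 0.479 with an estimated correlation), with rises of 0.41 in SETDB1, 0.38 in KMT2B and 0.33 in the DNA methyltransferase DNMT1. In the 6 fits without 1 library 2 to 8 of these enzymes rose and 0 or 1 fell, and DNMT1 did not pass without morphine replicate 1, 2 or 3 (adjusted p = 0.0524, 0.0561 and 0.0557). Of 4 clustered protocadherins PCDHB4 fell by 0.92 and PCDHGB5 rose by 0.24, also when adjusted over the list alone, and reads shared between such paralogs make both values uncertain. PCDHGB5 did not pass in any of the 6 fits without 1 library (adjusted p from 0.0552 to 0.0778).

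Groups of metabolism and stress held some changed genes, in libraries where astrocyte and microglia markers moved as given above. With 27.9% of all tested genes called, counts near or below that share do not show a response of a group. Of 24 heat shock and unfolded protein response genes 6 fell and 1 rose (6 and 2 adjusted over the list alone), among them the chaperones HSPA8 and DNAJA1, which fell by 0.44 and 0.45. Of these genes 3 rose and 8 fell in DESeq2, and 0 or 1 rose and 4 or 5 fell without 1 library. Of 41 nuclear-encoded oxidative phosphorylation genes 3 rose and 7 fell, also when adjusted over the list alone: UQCRH rose by 0.73 and COX7A2 by 0.69, and NDUFA5 fell by 0.67. In DESeq2 4 rose and 16 fell, and without 1 library 2 rose and 3 to 5 fell. Of 62 cytosolic ribosomal protein genes 8 rose and 5 fell (4 and 3 adjusted over the list alone), with RPS15A down by a log2 fold change of -0.94 and RPL13 up by 0.42. There were 19 rises and 10 falls in DESeq2, 10 and 3 with upper-quartile scaling, and 3 or 4 rises and 1 or 2 falls without 1 library. Ribosomal and respiratory genes have many processed copies, so that single values in these groups are uncertain. Of 17 clock genes 2 rose and 5 fell, also when adjusted over the list alone, with falls of 0.79 in NR1D2 (log2 fold change -0.79) and of 0.60 in CRY1 (log2 fold change -0.60), but 4 rose in DESeq2 and 0 rose and 3 to 5 fell without 1 library. Of 30 inflammation and interferon response genes 2 rose and 4 fell, also when adjusted over the list alone: MX2 rose by 1.74 and IFI44L fell 2.27 fold. Without 1 library 1 to 3 rose and 2 to 5 fell. Of 15 cholesterol synthesis genes 4 rose and 1 fell, also when adjusted over the list alone, with MVD up by 0.64 and LSS by 0.47. Without 1 library 1 to 3 rose, MVD did not pass without morphine replicate 1 or 2 (adjusted p = 0.0586 and 0.0575) and LSS did not without morphine replicate 1, 2 or 3 or saline replicate 2 (adjusted p = 0.0627, 0.0631, 0.0616 and 0.0623). Mitochondrially encoded transcripts were not analysed here.

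As whole lists, 0 of 27 passed the camera test of limma after Benjamini-Hochberg adjustment, and 6 had an unadjusted p under 0.05. The smallest adjusted p was 0.0681, shared by the histone and DNA modifying enzymes, the astrocyte markers and the oligodendrocyte precursor markers. With an estimated correlation between genes the smallest adjusted p was 0.479, with 2 lists at an unadjusted p under 0.05. In edgeR on the recovered reads, 2 lists passed: astrocyte markers, lower with morphine, and microglia markers, higher with morphine (each adjusted p = 0.0322). Over all alternatives the adjusted p of each of these lists ranged from 0.0322 to 0.479. The median, the mean and the test differed in sign for 6 lists: the glutamate, channel, monoamine, neurotrophin, oligodendrocyte and endothelial lists.

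**Figure D2:**
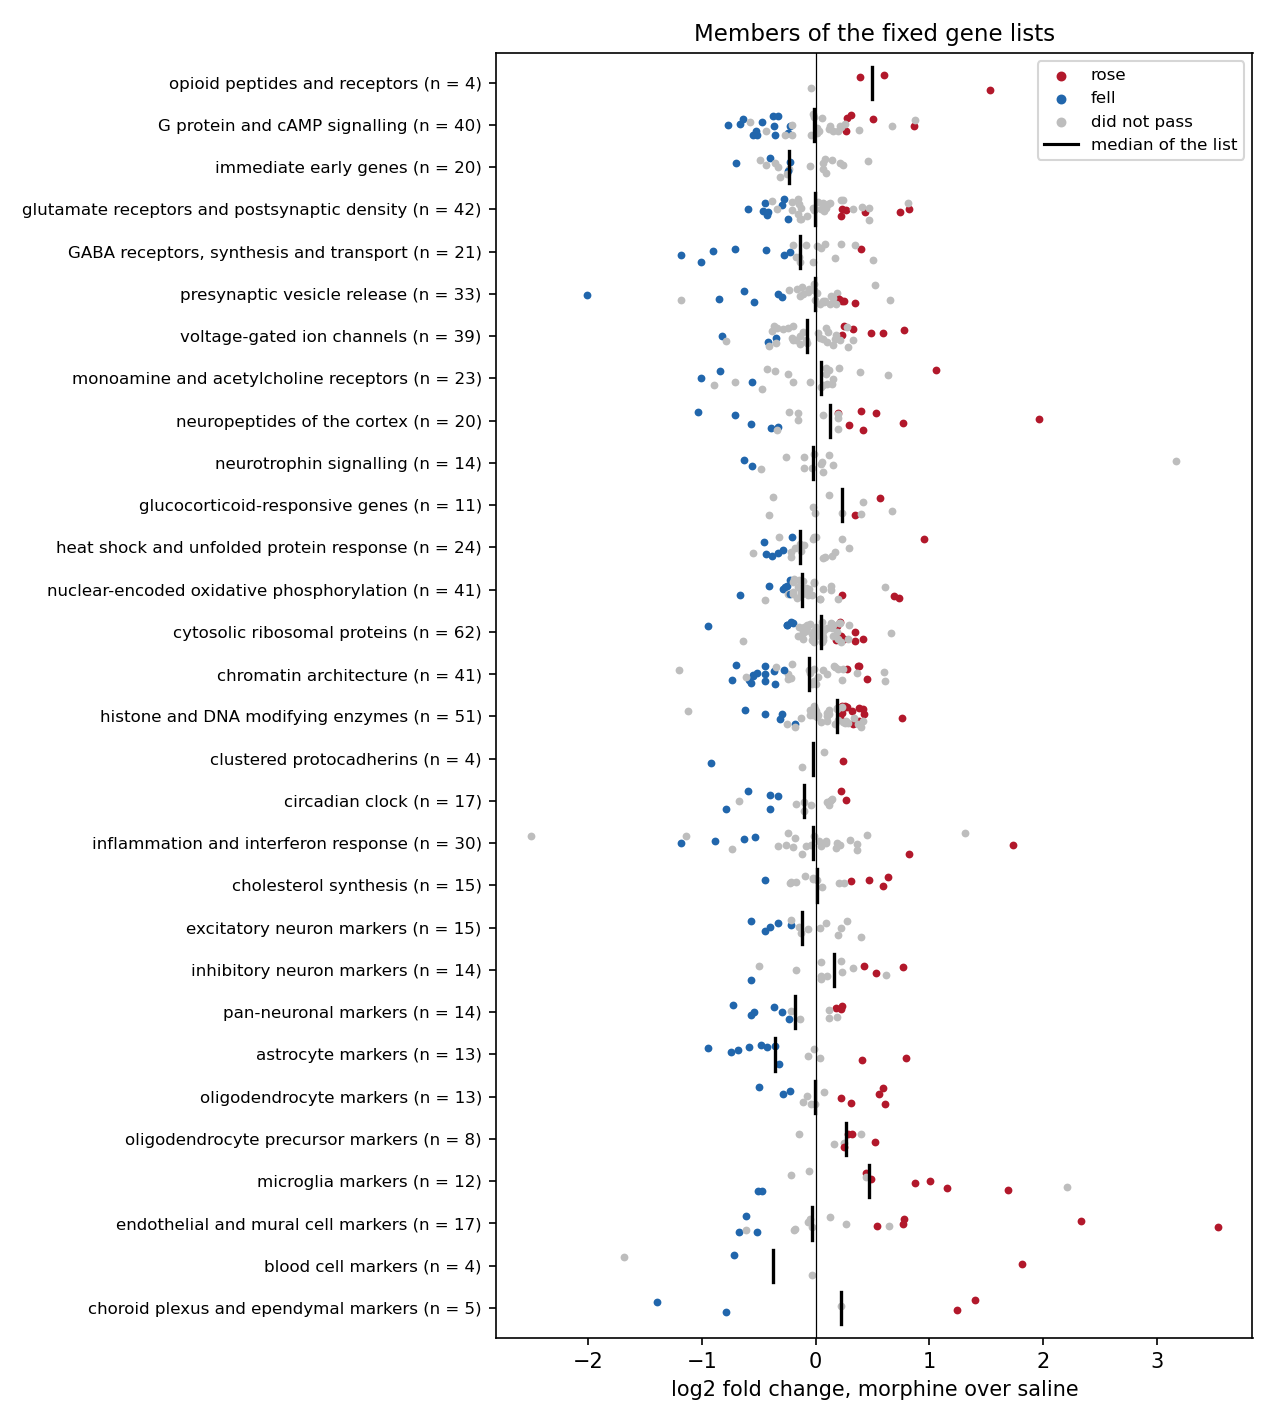
Log2 fold change, morphine over saline (horizontal axis), of each measured member of the gene lists (rows, n members each), coloured by whether it rose, fell or did not pass, with a black bar at the median of the list. In the astrocyte row 8 of 13 members fell, and in the microglia row 6 of 12 rose. Points are jittered vertically.

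**Figure D3:**
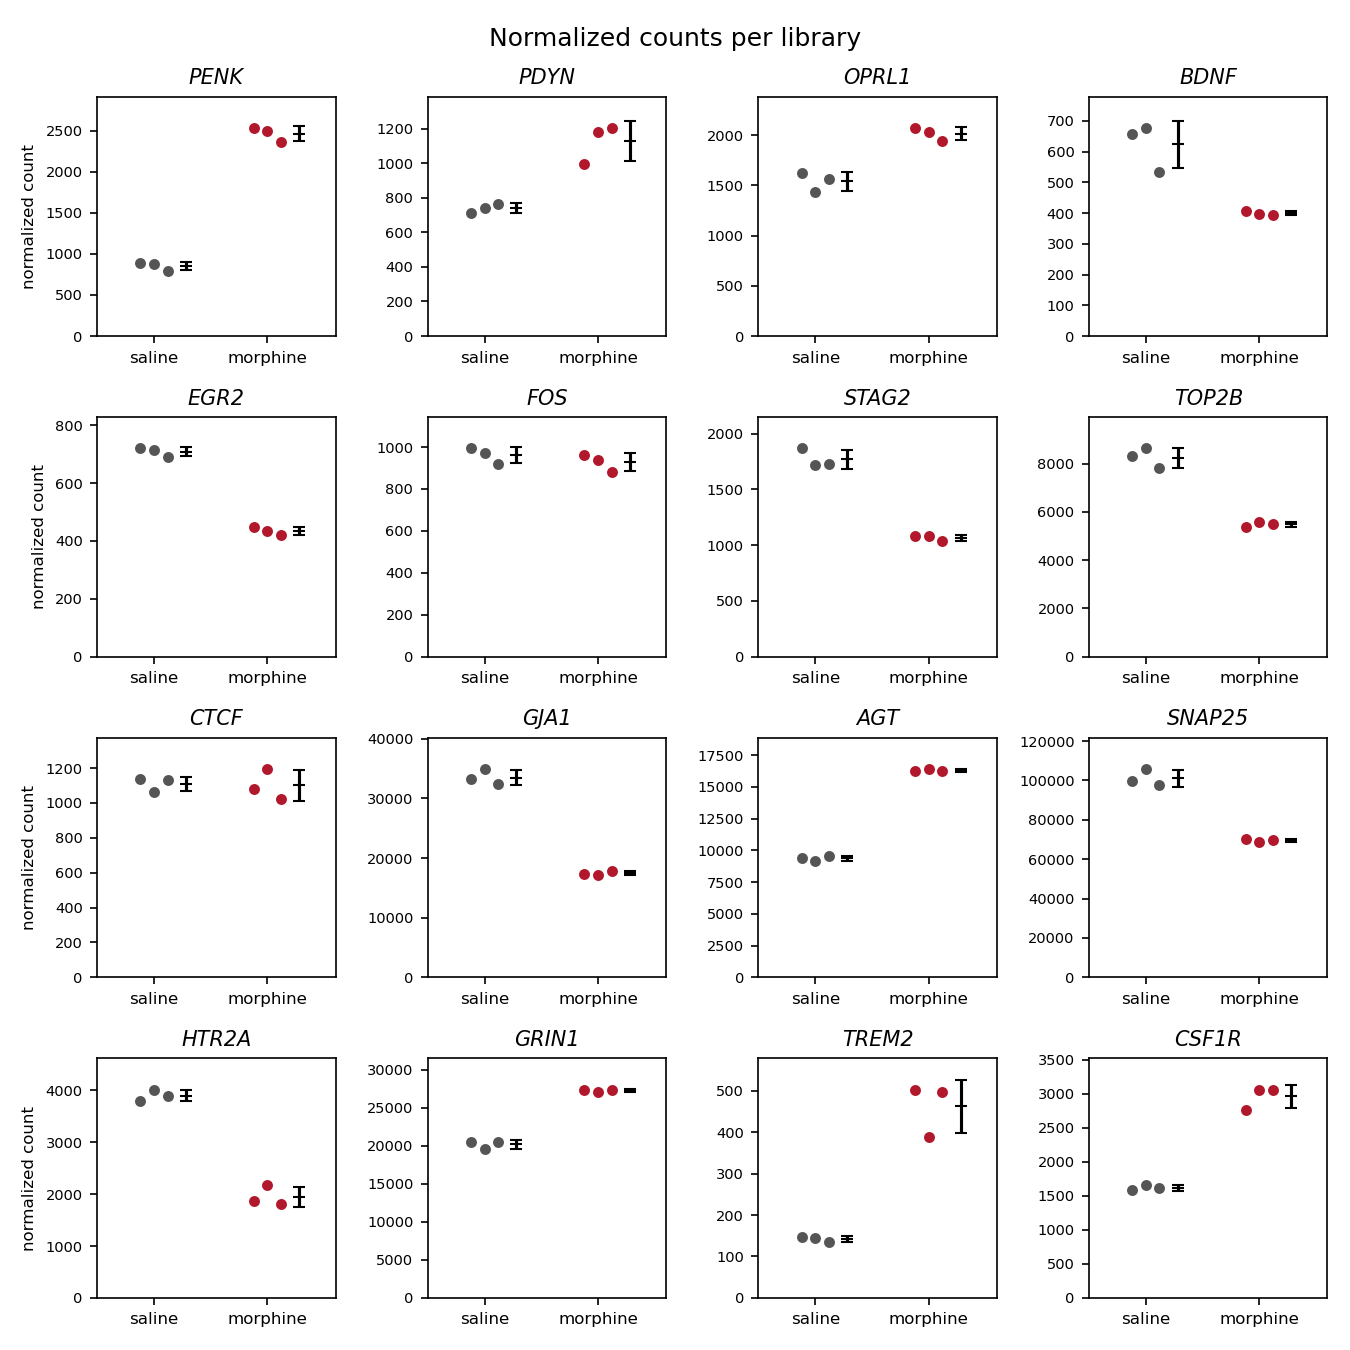
Normalized counts (vertical axes, starting at 0) of 16 genes in the 3 saline and 3 morphine libraries, with 1 point per library and the mean ± SD beside them. PENK lies between 793.1 and 883.1 in saline and between 2364 and 2536 in morphine libraries, while the CTCF values of the groups overlap.

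The authors' deposited table holds 5781 genes at an adjusted p under 0.05, with 2799 higher and 2982 lower in morphine libraries. Of the genes changed in the limma test, 4177 were also called in the authors' deposited table, all in the same direction. The limma test used the normalized counts of that same table, so the comparisons are not independent. A further 454 were called in limma only and 1481 in the authors' deposited table only, among the genes tested. A smaller deposited list of 2332 genes held all genes of over 1.5 fold with an unadjusted p under 0.05, and 481 of its genes had an adjusted p of 0.05 or more in the authors' deposited table. PENK, SYNDIG1L and SLC6A15 were called in both.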

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

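The edgeR test and limma with an intensity trend were chosen after the data had been seen. The count of 4631 changed genes was within 1.5 times under both other scalings, both pseudocounts, a minimum of 50, DESeq2, the authors' deposited table, edgeR and limma with a trend, with counts between 4584 and 5781. DESeq2 on the recovered reads gave the same 5781 genes as the authors' deposited table, so these are not separate alternatives. The count of changed genes was 2993 without a filter, where more low genes were tested, and 1532 at an adjusted p under 0.01. The count over 1.5 fold, 1726, was 911 at that threshold. Leaving out each library in turn gave 2536 to 3181 changed genes, with fewer samples in the fit, and 1358 to 1573 over 1.5 fold. The counts were 2686, 2536 and 2760 without morphine replicates 1, 2 and 3, and 3073, 2894 and 3181 without saline replicates 1, 2 and 3. With the replicate number as a block, 1577 genes changed, 1092 of them over 1.5 fold, and 43.2% rose. The numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.0563, -0.00392 and -0.0284, and no library correlated best with the library of its own number.

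The share of changed genes that rose, 46.3%, was 43.9% with TMM and 50.7% with upper-quartile scaling, which turned the balance. The median log2 fold change of all tested genes moved in step, from 0.0067 to -0.00367 with TMM and 0.0301 with the upper quartile. The balance of rises and falls thus depends on the scaling. The share that rose was 48.4% with DESeq2 and in the authors' deposited table, 47.9% with edgeR and with limma with a trend, 41.4% at an adjusted p under 0.01, and 41.7% to 47.1% without 1 library. TMM kept 97.1% of the calls and the upper quartile 95.8%. Camera called 0 lists in limma under each setting it was run with, the fits without 1 library included, and 2 in edgeR (the cause was not tested); it was not run on the DESeq2 fit. Of 131 genes named by the rule and past the threshold, 44 lost the call in some alternative, 41 of them under the block, and 4 other genes of the rule gained a call; 0 called directions changed. Leaving out 1 library ended between 12 and 21 of the named calls, in 23 genes in all, among them NAV1, OPRL1 and DRD2 as given above, ARC, FOSL2, NRGN, PCDHGB5, CSPG4 and TNR on leaving out each of the 6 libraries, and KLF10, LAMP5, SLC17A6, LSS, MVD, CD3E, CRY2, DNMT1, FOLR1, IL1R1, SUV39H1, TF and UGT8 on leaving out some of them.

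Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 4631 genes, the real split, and the highest other gave 2. OPRM1, with at most 5 reads in a library, was below the level for testing. With 10 splits no share under 0.05 can be reached. The other splits mix the animals of both groups as well as the treatments, so they do not separate treatment from animal.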

Other observations

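The tests of cell shares in astrocytes and microglia, and the lists of meningeal fibroblast, motile cilia and striatal projection neuron genes, were chosen after the gene table had been seen, as were the genes SLC13A4 and MYOC.

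Because the 3 added lists were chosen from these same data, their camera p-values are description only. They do not support a change of these lists and cannot be set beside those of the lists fixed beforehand. Of 32 measured genes of a meningeal fibroblast list 17 rose and 3 fell (12 to 14 and 2 without 1 library). Camera gave an adjusted p of 6.07e-05 over the 3 added lists and a p of 0.00829 with an estimated correlation. The falls were in COL5A2, ALDH1A1 and FN1 (log2 fold changes of -0.50, -0.42 and -0.21). SLC22A8, an organic anion carrier of brain barriers, had 347, 297 and 413 reads in the morphine libraries and 0, 3 and 3 in the saline libraries. FBLN2 rose by 1.95, the growth factor gene IGF2 by 1.88, the retinoid-binding CRABP2 by 3.00 and COL3A1 by 1.11. Outside the list, SLC13A4, a sulfate carrier, went from 47.73 to 789.9 normalized counts, and MYOC from 14.97 to 297.4 (n = 3 libraries per group). Of 20 motile cilia genes 6 rose and 1 fell (2 to 5 and 1 without 1 library), with a camera adjusted p of 0.0179 over the 3 added lists and a p of 0.0517 with an estimated correlation. Among them CFAP54 rose by 2.40 and HYDIN by 2.09, and SPAG17 fell by 2.80. Of 17 striatal projection neuron genes 2 rose and 1 fell (1 to 4 and 1 without 1 library), with a camera adjusted p of 0.477. RASGRP2 and DRD2 rose, and FOXP2 fell by a log2 fold change of -0.73. The median log2 fold change of the list was 0.0771 ± 0.254 (bootstrap SE), too uncertain to show or to exclude a shift of the list. Of the 22 genes of that list 6 are in other lists.

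There were 53 changed genes over 16 fold apart, 37 higher in morphine and 16 higher in saline. Of these, 21 had at most 3 reads in each library of a group, and 32.1% had no symbol against 21.9% of the other tested genes (Fisher's exact test, two-sided, p = 0.0945).

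Astrocyte markers fell in 8 of 13 cases. A lower share of astrocyte RNA in the morphine libraries that lowers all markers alike is argued against as the whole cause. In limma and under each alternative 2 markers, AGT and GFAP, rose past the threshold. Their largest adjusted p, under the replicate block, was 0.0426 for AGT and 0.0487 for GFAP. The test asked for 2 markers that rise, and that number was set after these rises had been seen. A lower share spread unevenly over astrocytes was not tested. All 8 falls passed with both other scalings. The median log2 fold change of all tested genes was 0.0067 at first, -0.00367 with TMM and 0.0301 with the upper quartile. Shifts this small could hardly end such calls, so a larger error of scaling was not tested. A change within astrocytes with treatment and a difference between the animals stay open; the design does not separate them and neither was tested. A part of the falls may still come from fewer astrocytes.

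Microglia markers rose in 6 of 12 cases. All 6 rises passed with both other scalings, which moved fold changes by little as given above, so a larger error of scaling was not tested. A higher share of microglial RNA in the morphine libraries, which could come from cells carried along in the purification, cannot be told apart from a change of state of microglia with treatment or a difference between the animals, which were not tested. The test asked for 2 markers that fall: P2RY12 and PTPRC fell in limma, but P2RY12 was the 1 marker to fall in DESeq2, where PTPRC had an adjusted p of 0.0741. The log2 fold change of PTPRC hardly differed, at -0.5107 in limma and -0.5059 in DESeq2. PTPRC passed in edgeR (adjusted p = 0.0317) and in limma with a trend (adjusted p = 0.0299). Its lost call in DESeq2 therefore does not speak for a higher share of microglial RNA. That the falls pass under each alternative was asked for only after these values had been seen.

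COL1A1 and COL1A2 rose by 3.54 and 2.34, and 2 of 2 passed with both other scalings, which moved fold changes by little as given above. A larger error of scaling was not tested. More meningeal fibroblast RNA in the morphine libraries is a candidate explanation: of 32 measured genes of the meningeal list, 31 of them at 10 or more normalized counts in saline, 17 rose and 3 fell. The median log2 fold change of the list, 0.544 ± 0.107 (bootstrap SE), lay below the bound of 1 set before that result was seen. By that bound the prediction was not met. Whether the bound suits genes with a high saline level was asked only afterwards. In saline, 13 of the 32 genes lay above the whole gain of COL1A2, 535 normalized counts. ALDH1A1 (20621 normalized counts in saline) and FN1 (3010) were among them. A gain of 535 normalized counts would raise such genes by less than 1 on the log2 scale. Most of the other 19 would then have to rise by 1 or more for the median to reach the bound. The bound therefore cannot decide the question. The 13 had a median of 0.0637, against 0.804 for the other 19, and both lie below 1. The saline level also enters the fold change, so part of this gap is built in, and the split does not decide it either. More meningeal fibroblast RNA was not told apart from a response to morphine or a difference between the animals. Purification of neurons would be meant to remove fibroblasts.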
